A study of Mus musculus with 8 samples.

How the data were processed

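Poly-A RNA was measured by sequencing in 8 libraries of mouse embryos at stage E9.25 with 9 to 11 somites. Per the labels, the embryos were wild type or homozygous for a Gcnf mutant allele, and each library held either an anterior piece, up to pharyngeal arch 1, or a posterior piece, from pharyngeal arch 2 on. Per the labels' protocols, tissue was kept in RNAlater before RNA was purified with a column kit, and libraries were made with a TruSeq kit that does not mark strand. Per the submitters' processing notes, CASAVA 1.8.2 and STAR were used with the mm10 genome build. The version of STAR, the annotation and the counting tool are not given in the sources used here.

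The authors deposited 1 table of TPM values (transcript abundance corrected for gene length and scaled to a fixed total), with 55421 Ensembl gene identifiers and 1 column for each of the 8 libraries, and each column summed to 1000000. Because TPM is relative to the total, a gene class that takes a larger share lowers every other value of that library. Names, coordinates and exon-union lengths came from the GENCODE mouse annotation, release M21, on the same build, and 55240 identifiers received a name and a length. In every library 22012 identifiers were at 0. Multiplying TPM by the exon-union length and scaling gave whole reads, within 0.01 read, for 98.8% to 98.89% of the values above 0. Among values under 100 reads the share was 98.91% to 99.16%. By this route the libraries held between 27064114 and 52957994 reads in genes. The number of genes above 0 was between 24717 and 26975. Mir6236, a small RNA gene that can collect reads of ribosomal RNA, was the highest in every library, at 19019.3 to 65296.8 TPM.

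Samples were grouped by genotype and region as the labels give them, 2 libraries in each of 4 groups. The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Genes with a TPM of at least 1 in at least 2 libraries were kept, which left 16699. The log2 of TPM plus 1 was fitted with limma 3.58.1 in R 4.3.3, with 4 group means, 4 residual degrees of freedom, 4.68 prior degrees of freedom and a trend of the spread on the mean. Contrasts were the genotype effect (mutant minus wild type) in each region, their difference (anterior minus posterior), and the region effect (posterior minus anterior) in each genotype. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. Differences are on the scale of log2(TPM + 1), which understates the change of low genes.

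For gene groups, 42 lists with 649 distinct genes were used, of which 1 gene was not matched to the table. Each of the 41 lists with at least 3 tested genes was tested with limma's camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a contrast. The same test with an estimated correlation is given beside it: no list passed it for either genotype effect or for their difference, and 3 lists passed it for each region effect. Called members were counted over all genes and with the adjustment over the list alone.

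The text names the targeted gene, the 10 largest rises and 10 largest falls of each genotype effect, and the 5 largest each way for the other contrasts. These had to pass the threshold, with a mean of at least 2 TPM in the higher group and no overlap between the libraries of both groups. Predicted genes, sex-linked genes and mitochondrial transcripts were left out of those. Up to 4 members of each list with the smallest p in a contrast could also be named. Egr2 and Mir6236, outside the rule, were chosen after their values were seen, as were the genes set beside Egr2 and the single tail genes. Some genes that the rule takes are not reported here. Where a named gene that passed was at 0 in both libraries of a group, a lower bound of its fold was computed against 3 reads in each library.

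The fit was tested on simulated data drawn from the real means, with 200 changed genes of 16300 in each of 5 draws. Changed genes were taken only from those above a minimum mean read count, so recovery of low genes was not simulated. Far fewer genes were changed than were called in the real data. For the anterior effect, 79.5% of 2-fold and 92.6% of 4-fold changes were recovered and 6.66% of calls were false. For the posterior effect the values were 80.5%, 96% and 5.39%. For the difference of effects, 0 false calls were made on average, and recovery of changed genes was not simulated. With camera, 25 of 25 simulated changed lists and 0 of 200 unchanged lists passed for the anterior effect. The same lists were used in all 5 draws, and every member of a changed list was raised. Simulated genes varied independently of each other, so false passes of lists whose genes move together could not appear. In the real data the estimated correlation reached 0.931, in the visceral endoderm list.

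Alternatives were other pseudocounts (0.1 and 0.5), no filter or a filter at 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without globin and mitochondrial genes, a robust or untrended spread, library weights, a fit on only the groups compared, a 2-fold threshold, a block for the replicate number, and leaving out each library in turn. Chosen after the data were seen were limma's voom on the recovered reads and leaving out both libraries numbered 159 or both numbered 153. A library left alone in its group was assumed to vary like the other groups. Reads shared between near-identical genes, such as globins and histones, and between overlapping or antisense genes cannot be told apart here. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9. Raw reads and transcript isoforms were not analysed here.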

Results

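RNA was sequenced from mouse embryos at stage E9.25, with 9 to 11 somites, that were either wild type or homozygous for a mutant allele of Gcnf. Gcnf, germ cell nuclear factor, is an orphan nuclear receptor encoded by Nr6a1. Each library came from either an anterior piece, holding the tissue in front of and including the first pharyngeal arch, or a posterior piece, holding the tissue from the second arch backwards. There were 8 libraries in 4 groups of 2, numbered 159 and 163 in the mutant groups and 153 and 156 in the wild-type groups. The labels do not say whether the 2 libraries of a group came from separate embryos. In both mutant groups library 159 had Xist (25.3 and 30.9 TPM) and library 163 had Ddx3y of the Y chromosome (31 and 39.4 TPM), so those 2 were not the same embryo. All 4 wild-type libraries had Ddx3y (26.2 to 31.9 TPM), so whether they came from separate embryos stays open, and p-values measure only the spread between these libraries. Sex is thus unequal between the genotypes. Leaving out both libraries numbered 159, an alternative chosen after the data were seen, left a lone mutant library in each region. The spread then came from the wild-type libraries alone, so the number of calls does not measure the effect of sex. Expression was given as TPM, transcript abundance scaled to a total of 1000000 per library, and the values corresponded to between 27064114 and 52957994 reads per library. A gene of 1 kb with 3 reads had a TPM of 0.2 in the deepest library and 0.403 in the shallowest, and such floors cover counting error only. Between the 2 libraries of a group, log2 values correlated across genes with r between 0.984 and 0.992, and genes are not independent replicates. Means below are given as TPM ± SD (n = 2 libraries), and changes as differences of log2(TPM + 1) ± standard error, which understate the change of low genes.

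Nr6a1 itself (ENSMUSG00000063972; mm10 chromosome 2, 38723370 to 38927688, minus strand) was abundant in all 4 groups. In the anterior pieces it reached 221 ± 27 TPM in the mutant and 199 ± 7.8 in the wild type, a difference of 0.14 ± 0.15 (limma, Benjamini-Hochberg adjusted p = 0.52). In the posterior pieces the means were 137 ± 30 and 161 ± 5.5, a difference of -0.25 ± 0.15 (adjusted p = 0.31). The deleted part of the allele is not given in the sources used here, and a value for the whole gene cannot separate mutant from normal transcript. These values therefore do not check the genotype labels, and "mutant" below means the libraries labelled as homozygous mutant.

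The anterior comparison asked which genes differed between mutant and wild-type tissue at and in front of the first pharyngeal arch. Pou5f1, which encodes the pluripotency factor Oct4, had the largest rise in the mutant, from 1.88 ± 0.095 to 111 ± 23 TPM (5.26 ± 0.16, adjusted p = 2.9e-06). Nanog, another pluripotency factor, rose from 0.987 ± 0.12 to 20.9 ± 1.8 TPM, while the list of 16 pluripotency and early epiblast genes held 3 rises and 1 fall, also adjusted over the list alone, and did not pass as a set (camera adjusted p = 0.094). The engrailed gene En2, a marker of the midbrain-hindbrain boundary, had the largest fall, from 60.0 ± 13 to 1.17 ± 0.32 TPM (-4.81 ± 0.21, adjusted p = 1.3e-05). Of the genes tested, 15 of 20 early neuronal and 23 of 30 hypoxia and glycolysis genes rose in the mutant, and 10 of 23 neural crest and 10 of 24 forebrain and midbrain genes fell.

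Of 16699 genes tested in the anterior pieces, 3937 passed the threshold, 2229 higher and 1708 lower in the mutant, and 926 of them differed at least 2-fold. The balance depended on scaling, with 2383 higher and 2334 lower under median-of-ratios scaling and 1948 higher and 2171 lower under quantile normalization. Besides Pou5f1, the largest rises were those of Cidea, a lipid droplet protein (5.01 ± 0.17), the peptide hormone Sst (4.56 ± 0.63), the transcription factor genes Bhlhe40 (4.28 ± 0.25), Bcl11b (3.95 ± 0.18), Bcl11a (3.71 ± 0.15), Nhlh1 (3.67 ± 0.33) and Nr0b1 (3.66 ± 0.22), the peptide hormone Adm (3.83 ± 0.35), and Ddit4, a stress-induced inhibitor of mTOR signalling (3.8 ± 0.24). Their adjusted p-values lay between 3.4e-06 for Cidea and 0.0017 for Sst, whose mutant libraries were far apart (31.5 ± 26 TPM). After En2, the largest falls were those of Wfikkn1 (-3.08 ± 0.16), Pax8 (-2.89 ± 0.18), Nkx2-9 (-2.77 ± 0.31), En1 (-2.68 ± 0.22), Ccl6 (-2.66 ± 0.23), Fgf17 (-2.61 ± 0.14), Pax5 (-2.43 ± 0.15), Flrt1 (-2.30 ± 0.17) and Sfrp5 (-2.25 ± 0.16). None of these 20 calls was lost when any 1 library was left out. The count of calls was 1545 without wild-type anterior library 153, 1840 without wild-type anterior library 156 and 2044 without mutant anterior library 163. It was 652 without both libraries numbered 153, an alternative chosen after the data were seen.

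**Figure D1:**
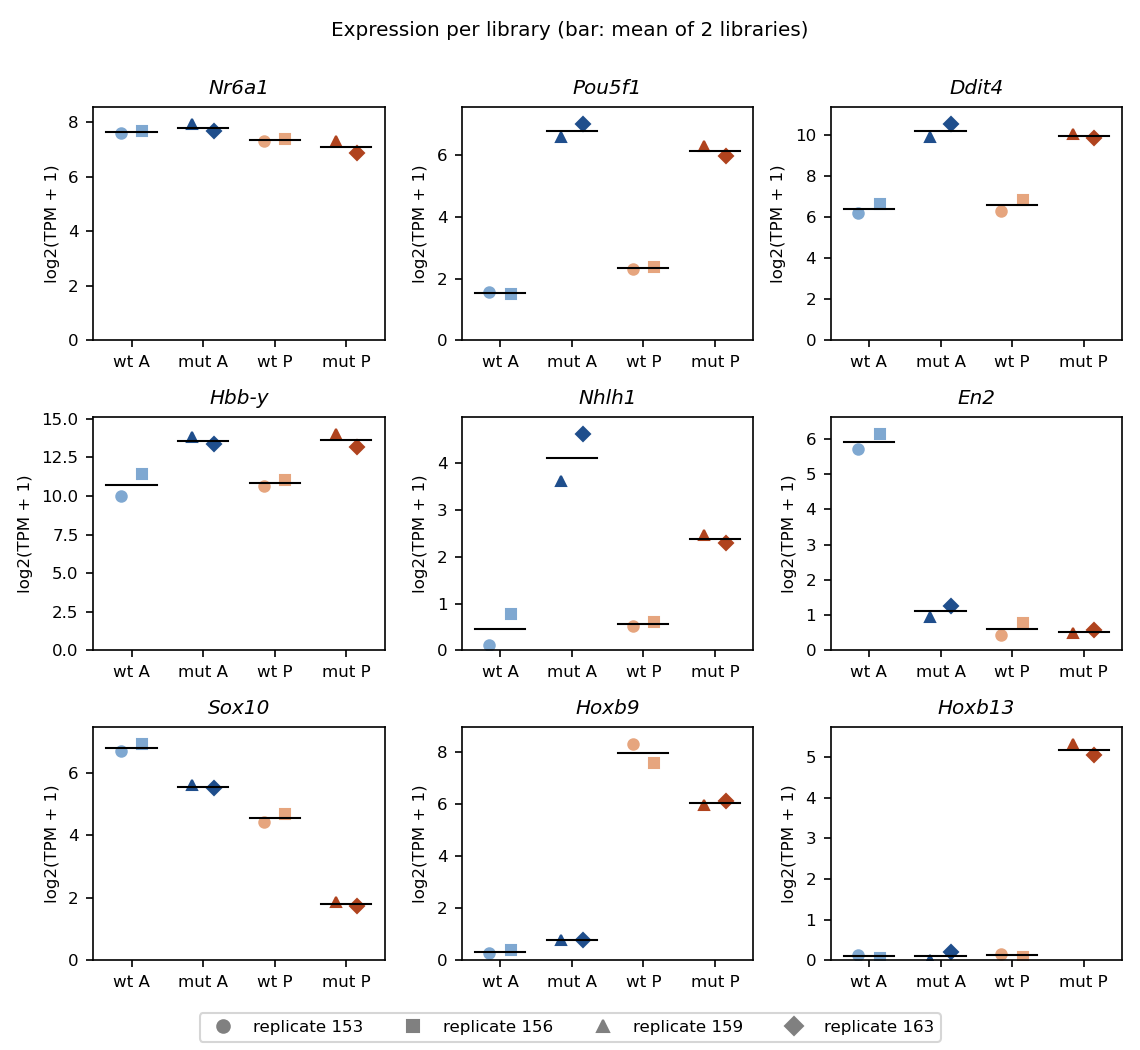
Log2(TPM + 1) of 9 genes in each library, with wild-type (wt) and mutant (mut) anterior (A) and posterior (P) pieces along the horizontal axis. Points are libraries, with shape giving the replicate number, and bars are means of 2 libraries. Nr6a1 had means between 137 and 221 TPM, Pou5f1, Ddit4, Hbb-y and Nhlh1 were higher in the mutant in both regions, and Hoxb13 reached 35.5 TPM in the mutant posterior pieces against 0.0932 in the wild-type ones.

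Among neural genes, 15 of the 20 tested members of the list of cranial ganglia and early neurons rose in the mutant anterior pieces and 0 fell (16 rose when adjusted over the list alone). Neurod4 rose from 0.346 ± 0.084 to 9.27 ± 0.37 TPM (2.93 ± 0.16, adjusted p = 3.2e-05), Elavl3, an RNA-binding protein of postmitotic neurons, from 1.51 ± 0.41 to 16.2 ± 3.2, and Neurod1 from 0.406 ± 0.088 to 7.12 ± 1.9. The list was higher as a set (camera adjusted p = 1.3e-09; adjusted p = 0.75 with an estimated correlation). Of 24 tested forebrain and midbrain genes, 10 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.004, and adjusted p = 0.75 with an estimated correlation). The falls included En2, En1 from 59.2 ± 5.8 to 8.41 ± 0.79 TPM, Pax5 from 37.9 ± 5.0 to 6.22 ± 0.65, and Pax2 from 16.2 ± 1.1 to 3.8 ± 0.11. The wild-type anterior libraries differed from each other in the hindbrain gene Egr2, chosen after its values were seen, at 6.87 TPM in library 153 and 0.338 in library 156. Library 153 was also higher in Hoxa2 (9.61 and 2.29 TPM), the heart gene Myl7 (75.3 and 8.67) and Ttr of the visceral endoderm (32.2 and 3.17). Library 156 was higher in the globin gene Hbb-y (2750 against 1010). Hoxb9 was at 0.324 TPM in library 156 and 0.207 in library 153. In those libraries 3 reads in a gene of 1 kb give 0.313 and 0.32 TPM, so little can be read from Hoxb9. Whether the cut differed was not tested. In the posterior pieces Egr2 was at 1.49 and 0.573 TPM in mutant libraries 159 and 163, and at 7.71 and 9.92 in wild-type libraries 153 and 156.

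Neural crest genes fell in part in the mutant anterior pieces. Of 23 tested specifiers and genes of migratory crest, 10 fell and 1 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.0072, and adjusted p = 0.75 with an estimated correlation). Sox10 fell from 112 ± 12 to 46.3 ± 2.1 TPM (-1.25 ± 0.13, adjusted p = 0.00042), Sox8 from 4.25 ± 0.04 to 0.72 ± 0.15, and Ets1 from 58.9 ± 1.0 to 29.2 ± 1.6. The list test was no longer passed with a filter at 5 TPM (adjusted p = 0.051). Of 22 tested genes of crest-derived arch mesenchyme, 4 fell and 1 rose, and the set did not pass (camera adjusted p = 0.094). In that list Dlx2 fell from 34.3 ± 3.3 to 13.2 ± 5.7 TPM. Of 17 Fgf pathway genes, 7 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0072, and adjusted p = 0.75 with an estimated correlation). Fgf17 fell from 38.3 ± 2.3 to 5.45 ± 0.55 TPM and Etv5, a transcription factor induced by Fgf signalling, fell by 1.48 ± 0.12 on the log2 scale, while the receptor gene Fgfr2 rose from 33.9 ± 2.0 to 68.2 ± 0.99.

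Hypoxia and glycolysis genes formed the set with the smallest p in the anterior pieces. Of 30 tested, 23 rose and 0 fell (25 rose when adjusted over the list alone; camera adjusted p = 1.4e-12, and adjusted p = 0.75 with an estimated correlation). Ddit4 rose from 85.3 ± 18 to 1220 ± 370 TPM, Bnip3 from 22.6 ± 6.8 to 91.6 ± 12, and Aldoc from 4.30 ± 0.34 to 32.6 ± 6.4. Primitive erythroid genes rose beside them, with 12 of 20 higher and 0 lower (15 higher adjusted over the list alone; camera adjusted p = 4e-05, and adjusted p = 0.80 with an estimated correlation). The embryonic globin gene Hbb-y rose from 1880 ± 1200 to 12400 ± 2900 TPM (2.87 ± 0.44, adjusted p = 0.0027), and globin genes together made up 3.51% ± 1.3 of TPM in the mutant and 0.714% ± 0.407 in the wild type. Some globin genes, such as Hba-a1 and Hba-a2, are near-identical copies, so those single members are uncertain. Of 22 genes of the integrated stress response, 9 rose and 0 fell (11 rose when adjusted over the list alone; camera adjusted p = 0.00069, and adjusted p = 0.80 with an estimated correlation), among them Trib3 (3.35 ± 0.34), Chac1 (3.25 ± 0.38) and Vldlr (1.87 ± 0.18).

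Lists of chromatin, cell cycle and timing genes were also tested in the anterior pieces. Of 17 replication-dependent histone genes, 7 rose and 0 fell (9 rose when adjusted over the list alone; camera adjusted p = 0.00067, and adjusted p = 0.80 with an estimated correlation), with Hist1h1c going from 16.7 ± 2.1 to 42.2 ± 1.3 TPM. Histone genes share sequence, and most of their transcripts lack a poly-A tail, so these values are uncertain. Of 20 DNA replication genes, 4 fell and 0 rose, the same counts adjusted over the list alone (camera adjusted p = 0.004, and adjusted p = 0.80 with an estimated correlation), and Ccne1, which encodes cyclin E1, fell from 262 ± 6.7 to 107 ± 9.9 TPM. Of 10 genes of the Lin28 and let-7 timing list, 3 fell and 0 rose (4 fell when adjusted over the list alone; camera adjusted p = 0.0071, and adjusted p = 0.80 with an estimated correlation). Hmga2 in that list fell from 290.0 ± 10 to 194 ± 0.42 TPM. Of 8 mitochondrial transcripts only mt-Nd1 passed, from 8030 ± 2700 to 3270 ± 1100 TPM (-1.29 ± 0.32, adjusted p = 0.02), and its call was lost without mutant anterior library 163 or wild-type anterior library 153 (adjusted p = 0.12 in each). The mitochondrial set passed with camera (adjusted p = 0.042, and adjusted p = 0.80 with an estimated correlation), with 1 fall adjusted over the list alone. It was lost without any of 4 libraries: mutant anterior 163 (adjusted p = 0.16), wild-type anterior 153 (0.11), wild-type posterior 153 (0.076) and wild-type posterior 156 (0.072), without both libraries numbered 153 (0.13), under median-of-ratios scaling (0.099) and with a filter at 5 TPM (0.054).

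The posterior comparison asked the same question of the tissue from the second arch backwards. Hoxb13, the most 5' gene of its cluster, had the largest rise, from 0.0932 ± 0.041 to 35.5 ± 4.8 TPM (5.06 ± 0.18, adjusted p = 5.1e-06). Pou5f1 rose from 4.06 ± 0.16 to 69.6 ± 11 TPM (3.79 ± 0.16, adjusted p = 1.5e-05), and Nanog from 0.479 ± 0.085 to 4.36 ± 0.97, and the pluripotency list held 7 rises and 3 falls, also adjusted over the list alone, without passing as a set (camera adjusted p = 0.096). Sox10 fell from 22.6 ± 3.0 to 2.49 ± 0.18 TPM (-2.75 ± 0.13, adjusted p = 1.9e-05). Of the genes tested, 9 of 10 in Hox paralogue groups 10 to 13 rose, while 4 of 12 in groups 6 to 9 and 3 of 15 markers of visceral endoderm fell.

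In the posterior pieces 1919 of the 16699 genes passed, 1430 higher and 489 lower, and 625 of them differed at least 2-fold. The share of higher calls was 74.5%, against 54.3% of 2521 calls under median-of-ratios scaling and 53.9% of 2276 calls under quantile normalization. After Hoxb13, the largest rises were those of Cidea (4.77 ± 0.17), Fabp7, a fatty acid binding protein of radial glia (3.90 ± 0.41), Nr0b1 (3.85 ± 0.22), Pou5f1, the platelet chemokine gene Pf4 (3.63 ± 0.44), Bhlhe40 (3.44 ± 0.25), Ier3 (3.41 ± 0.19), Bcl11a (3.40 ± 0.15) and Ddit4 (3.38 ± 0.24). The count of calls was 383 without wild-type posterior library 153 and 625 without wild-type posterior library 156. It was 180 without both libraries numbered 153, 934 when only the posterior libraries entered the fit, 954 without a filter on low values and 1102 with library weights.

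The falls of the posterior pieces held a group of genes that the visceral endoderm and liver express, with a wide spread between the mutant libraries. These were Spp2 (-3.71 ± 0.54, adjusted p = 0.0043), Apoa4 (-2.89 ± 0.77, adjusted p = 0.046), Slc2a2 (-2.79 ± 0.71, adjusted p = 0.039), Fga (-2.73 ± 0.58, adjusted p = 0.02) and Fgg (-2.28 ± 0.48, adjusted p = 0.02), with Car7 (-3.15 ± 0.69, adjusted p = 0.023) and Mir7688 (-2.64 ± 0.55, adjusted p = 0.019) beside them. All 7 calls were lost without wild-type posterior library 153 (adjusted p = 0.073 for Spp2, 0.23 for Apoa4, 0.19 for Slc2a2, 0.15 for Fga and Car7, and 0.16 for Fgg and Mir7688). Apoa4, Slc2a2, Fga, Fgg and Car7 were also lost without wild-type posterior library 156 (adjusted p = 0.16, 0.16, 0.099, 0.086 and 0.12). Apoa4 and Slc2a2 were lost as well without mutant posterior library 159 (adjusted p = 0.079 and 0.074), mutant anterior library 159 or mutant anterior library 163 (0.063 and 0.054 in each). The falls of Sox10, Cer1, from 14.3 ± 0.52 to 1.61 ± 0.32 TPM, and Bhlha9, from 17.5 ± 2.0 to 2.61 ± 0.21, kept their calls without any 1 library.

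Hox genes of the posterior pieces were tested in lists by paralogue group. Of 10 tested genes of groups 10 to 13, 9 rose and 0 fell, the same counts adjusted over the list alone (camera adjusted p = 2.3e-11, and adjusted p = 0.12 with an estimated correlation), and the list's median was 2.37. The list held 12 genes before the filter on low values. Hoxb13 and Hoxd12 passed that filter only through the mutant posterior libraries, so the share of rises is in part a result of the filter. Hoxb13 (ENSMUSG00000049604) lies on mm10 chromosome 11, 96194316 to 96197447, plus strand. Hoxa13 (chromosome 6, 52257694 to 52260880) rose from 2.38 ± 0.056 to 18.9 ± 0.14 TPM and Hoxd13 (chromosome 2, 74668310 to 74671599) from 4.93 ± 0.61 to 38.2 ± 2.1. Hoxd12 (chromosome 2, 74675013 to 74677705) was listed at 0 in both wild-type posterior libraries and at 8.49 ± 0.90 TPM in the mutant, at least 53.3-fold higher than 3 reads in either library would give. With Hoxd12 at that bound the median of the list was also 2.37. Of 12 genes of groups 6 to 9, 4 fell and 0 rose (6 and 1 adjusted over the list alone; camera adjusted p = 2.1e-05, and adjusted p = 0.61 with an estimated correlation). Hoxb9 (chromosome 11, 96271457 to 96276595) fell from 255 ± 87 to 65.8 ± 4.7 TPM (-1.90 ± 0.20, adjusted p = 0.0012) and Hoxc8 (chromosome 15, 102990607 to 102994111) from 77.8 ± 22 to 16.0 ± 1.9. Of 15 genes of groups 1 to 5, 2 rose and 0 fell, and the set did not pass (camera adjusted p = 0.22).

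**Figure D2:**
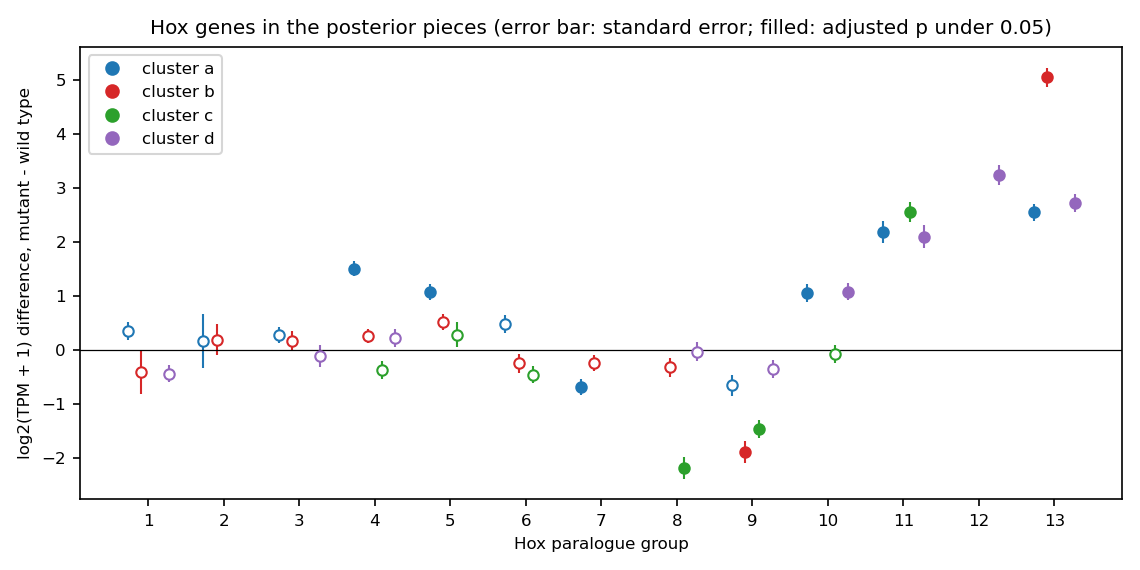
Difference of log2(TPM + 1) between mutant and wild-type posterior pieces for each tested Hox gene, by paralogue group along the horizontal axis and colored by cluster. Bars are standard errors, and filled points passed an adjusted p of 0.05. Groups 10 to 13 lie above 0 with a median of 2.37 apart from 1 open point in group 10, while the filled points of groups 6 to 9 lie below 0. Hoxd12 was listed at 0 in the wild type, so its point depends on the added 1 TPM.

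Some lists of mesodermal and signalling genes passed in the posterior pieces and others did not. Somite genes held 0 calls of 14 (camera adjusted p = 0.82), presomitic mesoderm 2 rises and 1 fall of 17 (0.88), the Fgf pathway 2 and 4 of 17 (0.48) and Wnt targets 1 and 1 of 13 (0.97). Adjusted over the list alone, these were 0, 2 and 1, 3 and 4, and 2 and 1. Of 14 limb and lateral plate genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00053, and adjusted p = 0.30 with an estimated correlation). Tbx4, a hindlimb and allantois regulator, rose from 8.56 ± 0.63 to 60.9 ± 7.7 TPM (2.69 ± 0.16, adjusted p = 7.2e-05). Of 16 Bmp pathway genes, 5 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.61 with an estimated correlation). Bmp4 rose from 61.4 ± 3.0 to 119 ± 0.017 TPM and its antagonist Bambi from 41.5 ± 1.1 to 83.4 ± 9.8, and the set was lost without wild-type posterior library 153 (adjusted p = 0.08) or both libraries numbered 153 (0.088). Of 15 hedgehog pathway genes, 4 rose and 0 fell (5 rose when adjusted over the list alone; camera adjusted p = 0.043, and adjusted p = 0.61 with an estimated correlation). That set was lost without mutant posterior library 159 (adjusted p = 0.20), wild-type posterior library 153 (0.26), both libraries numbered 159 or both numbered 153 (0.18 in each), or under median-of-ratios scaling (0.062). Of 11 genes of intermediate mesoderm and kidney, 4 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.00083, and adjusted p = 0.61 with an estimated correlation), and the falls of Pax8 (-2.13 ± 0.18), Ret (-2.04 ± 0.18) and Pax2 (-1.98 ± 0.18) kept their calls without any 1 library.

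Lists of neural genes were also tested in the posterior pieces. Of 20 genes of cranial ganglia and early neurons, 11 rose and 1 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.0044, and adjusted p = 0.61 with an estimated correlation). That set was lost without both libraries numbered 159, an alternative chosen after the data were seen (adjusted p = 0.062). Neurog1 rose from 2.27 ± 0.84 to 17.8 ± 2.6 TPM (2.54 ± 0.21, adjusted p = 0.00041), and Neurog2 from 11.4 ± 0.41 to 31.7 ± 4.1. Of 19 neural progenitor genes, 7 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.61 with an estimated correlation). Fabp7 in that list rose from 14 ± 9.2 to 202 ± 35 TPM, and Hes3 fell from 45.4 ± 7.8 to 21.7 ± 1.2. That set was lost without mutant posterior library 159 (adjusted p = 0.089) or wild-type posterior library 153 (0.34), under median-of-ratios scaling (0.052), with voom on recovered reads (0.056), and without both libraries numbered 159 (0.072) or both numbered 153 (0.27). Forebrain and midbrain genes held 2 rises and 4 falls of 24 and hindbrain genes 0 and 1 of 14, the same counts adjusted over the list alone, and neither set passed (camera adjusted p = 0.13 and 0.16). Neural crest genes went both ways, with 5 of 23 lower and 4 higher (9 and 6 adjusted over the list alone; camera adjusted p = 0.16). Foxd3 fell from 15.2 ± 3.4 to 3.09 ± 1.4 TPM with Sox10, and Rxrg rose from 1.84 ± 0.031 to 6.30 ± 0.31.

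Hypoxia and erythroid lists were tested in the posterior pieces too. Of 30 hypoxia and glycolysis genes, 21 rose and 0 fell (26 rose when adjusted over the list alone; camera adjusted p = 1e-15, and adjusted p = 0.61 with an estimated correlation). Ddit4 rose from 95.8 ± 24 to 994 ± 96 TPM, Ankrd37 from 8.19 ± 0.021 to 29.3 ± 1.6, and Egln3, a prolyl hydroxylase of the hypoxia response, from 26.2 ± 1.5 to 106 ± 9.6. Of 20 erythroid genes, 8 rose and 0 fell (13 rose when adjusted over the list alone; camera adjusted p = 2.8e-05, and adjusted p = 0.67 with an estimated correlation). Globin genes made up 3.35% ± 1.56 of TPM in the mutant and 0.704% ± 0.0919 in the wild type. The rise of Hbb-y (2.76 ± 0.44, adjusted p = 0.0062) was lost without wild-type posterior library 153 (2.54, adjusted p = 0.09). Of 22 genes of the integrated stress response, 8 rose and 0 fell (11 rose when adjusted over the list alone; camera adjusted p = 0.00011, and adjusted p = 0.61 with an estimated correlation), among them Stc2 (1.55 ± 0.17) and Ddit3 (1.24 ± 0.14).

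Visceral endoderm genes of the yolk sac were tested as a set in the posterior pieces. Of 15 tested, 3 fell and 0 rose (7 fell when adjusted over the list alone), with a median of -1.92 (camera adjusted p = 2.4e-06, and adjusted p = 0.61 with an estimated correlation). The libraries of a group differed widely in them. Afp, alpha-fetoprotein, was at 13.8 and 66.4 TPM in mutant posterior libraries 159 and 163, and at 396 and 266 in wild-type posterior libraries 153 and 156 (-3.37 ± 0.97, adjusted p = 0.057). In the anterior pieces Afp reached 21.7 TPM in wild-type library 153, against 1.30 in wild-type library 156. The heart genes Myl7 and Tnnt2, chosen after their values were seen, also differed widely within groups. In mutant posterior libraries 159 and 163, Myl7 was at 1800 and 218 TPM and Tnnt2 at 54.7 and 9.76. In wild-type posterior libraries 153 and 156, Myl7 was at 233 and 707 and Tnnt2 at 9.69 and 28.2. The heart list passed with 4 genes higher and 0 lower of 23, the same counts adjusted over the list alone (camera adjusted p = 0.042, and adjusted p = 0.72 with an estimated correlation). Its direction turned without mutant posterior library 159 (adjusted p = 0.92) or wild-type posterior library 153 (0.93), while Tbx5 in it rose from 9.01 ± 0.27 to 20.5 ± 2.5 TPM and kept its call.

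Timing and cell cycle sets passed in the posterior pieces with few called members. Of 10 genes of the Lin28 and let-7 timing list, 3 fell and 0 rose (6 fell when adjusted over the list alone; camera adjusted p = 0.00024, and adjusted p = 0.61 with an estimated correlation). Lin28a fell from 929 ± 33 to 550.0 ± 58 TPM (-0.76 ± 0.12, adjusted p = 0.0057), a call lost without wild-type posterior library 153 (-0.72, adjusted p = 0.07). Of 20 DNA replication genes only Ccne1 fell, from 187 ± 20 to 99.9 ± 6.9 TPM, also when adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.67 with an estimated correlation), and that set was lost without wild-type posterior library 153 (adjusted p = 0.055) or both libraries numbered 153 (0.051). Of 18 mitotic genes 0 passed with limma, over all genes or adjusted over the list alone, and the set passed downwards (camera adjusted p = 0.034, and adjusted p = 0.67 with an estimated correlation). It was lost without mutant posterior library 163 (adjusted p = 0.15), wild-type posterior library 153 (0.20) or both libraries numbered 153 (0.18). Of 17 histone genes, 1 fell and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.67 with an estimated correlation), and this set was lost without wild-type posterior library 156 (adjusted p = 0.87) and under median-of-ratios scaling (0.076).

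**Figure D3:**
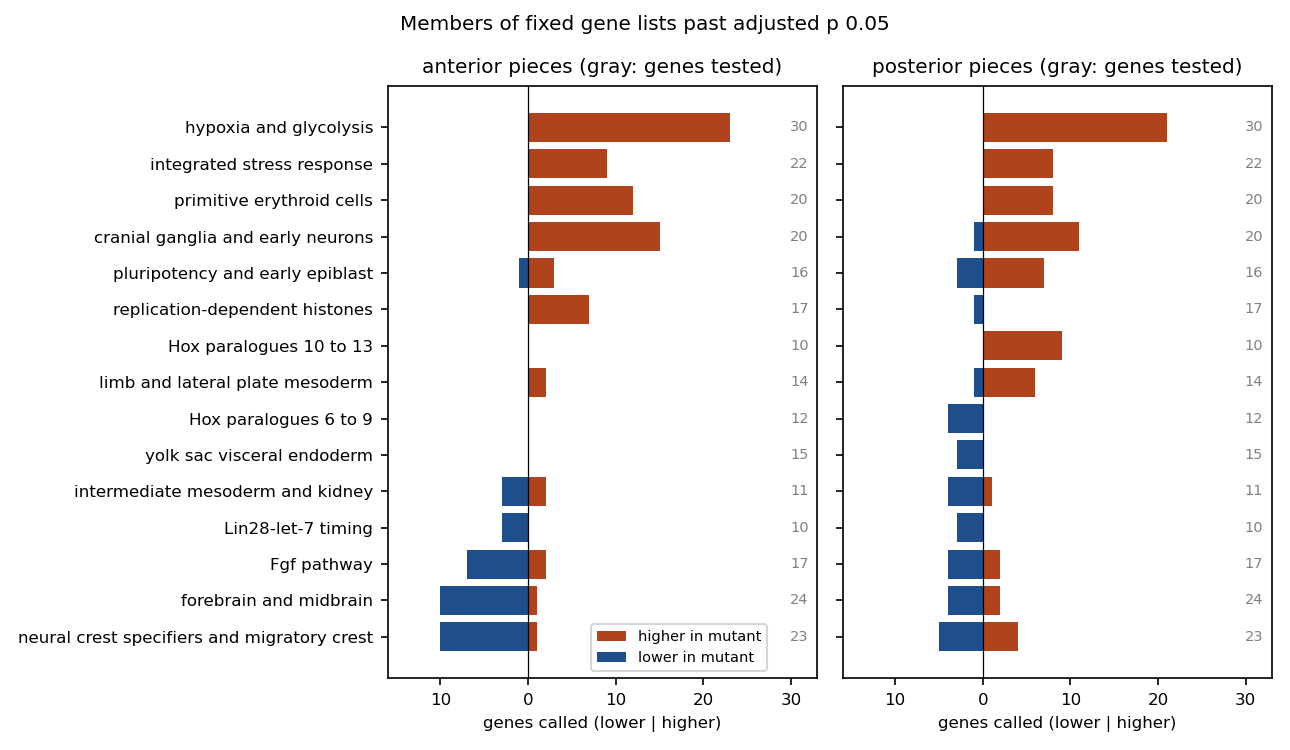
Number of genes past an adjusted p of 0.05 in 15 gene lists, higher in the mutant (bars to the right of 0) or lower (bars to the left), in the anterior pieces (left panel) and the posterior pieces (right panel). Gray numbers give the genes tested per list. In the anterior pieces 23 of 30 hypoxia and glycolysis genes were higher, in the posterior pieces 21 of 30, and 9 of 10 genes of Hox groups 10 to 13 were higher in the posterior pieces.

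The genotype effects of both regions were set side by side. In both, Pou5f1, Cidea, Nr0b1, Bhlhe40, Bcl11a and Ddit4 were among the 10 largest rises. A total of 1214 genes passed in the same direction in both regions, 947 higher and 267 lower, against 191 and 50 for independent lists of these sizes. These were 63.3% of the posterior and 30.8% of the anterior calls, and 36 genes passed in opposite directions. Under median-of-ratios scaling 923 higher and 759 lower were shared, against 196 and 161. Changes correlated across genes with r = 0.595, and genes are not independent replicates. Both effects used the same estimate of each gene's spread, so their calls can overlap more than independent lists would. Pieces with the same number may also share an embryo, which the labels do not state, so this overlap is a description with no test. Shared genes fell to 298 without wild-type posterior library 153, 446 without wild-type posterior library 156, 678 without wild-type anterior library 153, 750 without wild-type anterior library 156 and 111 without both libraries numbered 153. Without mutant anterior library 163, 817 were shared.

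The difference between the regions in the genotype effect was tested as an interaction, with positive values where the effect in the anterior pieces was the higher. Hoxb13 differed most (-5.05 ± 0.26, adjusted p = 0.00029), and its means in the anterior pieces were 0.0762 TPM in the mutant and 0.0720 in the wild type. En2 followed (-4.75 ± 0.29, adjusted p = 0.00059), with little transcript in either posterior group (0.449 ± 0.051 TPM in the mutant, 0.523 ± 0.26 in the wild type). Gfra3, a receptor subunit for the neurotrophic factor artemin, rose in the posterior pieces from 13 ± 3.5 to 81.0 ± 7.5 TPM and was at 2.94 ± 0.11 in the mutant and 5.07 ± 0.15 in the wild-type anterior pieces (-3.19 ± 0.24, adjusted p = 0.0014). Cyp26a1, which degrades retinoic acid, went from 21.2 ± 1.1 to 74.9 ± 17 TPM in the anterior pieces and from 84.1 ± 6.0 to 56.4 ± 3.4 in the posterior ones (2.32 ± 0.21, adjusted p = 0.0033). Fgf17 (-2.41 ± 0.19, adjusted p = 0.0022) and Uap1l1 (2.66 ± 0.17, adjusted p = 0.00059) also differed, and all 6 calls held without any 1 library.

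In all, 169 genes passed the interaction test, 69 with the higher effect in the anterior and 100 in the posterior pieces. With the replicate number as a block, 290 (random) or 115 (fixed) passed. The count was 20 without wild-type posterior library 153, 24 without wild-type posterior library 156, 61 and 74 without wild-type anterior libraries 153 and 156, and 88 without mutant anterior library 159 or 163. It was 199 without mutant posterior library 159, and 209 without mutant posterior library 163, where the balance turned to 116 with the higher effect in the anterior and 93 in the posterior pieces. With limma it was 0 without both libraries numbered 153, where 1031 genes had an unadjusted p under 0.05, and 55 without a filter on low values. Of the 10 genes of Hox groups 10 to 13, 7 differed with the higher effect in the posterior pieces (9 adjusted over the list alone; camera adjusted p = 3.4e-16, and adjusted p = 0.059 with an estimated correlation). Of the 12 genes of groups 6 to 9, 3 differed the other way (4 adjusted over the list alone; camera adjusted p = 4e-07, and adjusted p = 0.44 with an estimated correlation), with Hoxb9 at 2.34 ± 0.29. Both Hox lists had a median anterior effect of 0.04 and 0 anterior calls, so these differences mainly restate the posterior effects. Neural crest genes did not pass as a set, and Sox10 differed with the deeper fall in the posterior pieces (1.5 ± 0.18, adjusted p = 0.0092), a call lost without wild-type posterior library 156 (1.37, adjusted p = 0.065).

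Posterior against anterior pieces were compared within each genotype to see what the dissection separated. In the wild type, 2422 genes passed, 1312 higher in the posterior and 1110 in the anterior pieces. The split was 1583 and 946 under median-of-ratios scaling and 1535 and 1707 with library weights. Hoxb9 (7.62 ± 0.20), the antisense transcript Hoxb5os (7.51 ± 0.22), Cdx4 (7.36 ± 0.21), Cdx2 (7.01 ± 0.17) and Nepn (6.90 ± 0.20) were the most posterior, each with adjusted p = 2.2e-07, and the library kit did not mark strand, so Hoxb5os cannot be told apart from overlapping Hox transcripts. Otx2 (-5.68 ± 0.30, adjusted p = 4.9e-06), En1 (-5.66 ± 0.22), En2 (-5.32 ± 0.21), Lhx5 (-4.95 ± 0.16) and Six3 (-4.91 ± 0.13) were the most anterior. Of 24 forebrain and midbrain genes, 23 were lower in the posterior pieces, also adjusted over the list alone (camera adjusted p = 9.4e-31, and adjusted p = 0.032 with an estimated correlation). Of 14 limb and lateral plate genes, 10 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 4.1e-15, and adjusted p = 0.032 with an estimated correlation), and of 10 genes of Hox groups 10 to 13, 8 were higher, also adjusted over the list alone (camera adjusted p = 3.1e-11, and adjusted p = 0.045 with an estimated correlation). All 15 genes of Hox groups 1 to 5 and all 12 of groups 6 to 9 were higher, over all genes and adjusted over the list alone (camera adjusted p = 1e-29 and 1.5e-29), with adjusted p = 0.053 and adjusted p = 0.054 with an estimated correlation. All 15 visceral endoderm genes were higher in the posterior pieces, also adjusted over the list alone (camera adjusted p = 1e-13, and adjusted p = 0.26 with an estimated correlation). The count of calls was 1182 without wild-type posterior library 156, 1201 without wild-type anterior library 156, 1232 without wild-type posterior library 153, 1504 without wild-type anterior library 153, and 573 without both libraries numbered 153.

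In the mutant, 2690 genes passed, 1337 higher in the posterior and 1353 in the anterior pieces (1595 and 1362 under median-of-ratios scaling). Msgn1, a regulator of presomitic mesoderm, was the most posterior, at 131 ± 7.9 against 0.0820 ± 0.12 TPM (6.94 ± 0.18, adjusted p = 1.6e-07), and Hoxb5os (6.85 ± 0.22), Nepn (6.78 ± 0.20), Cdx4 (6.02 ± 0.21) and Hoxa5 (5.95 ± 0.15) followed. The retinoic acid synthase gene Aldh1a3 was the most anterior, at 131 ± 19 against 0.354 ± 0.0093 TPM (-6.60 ± 0.15, adjusted p = 1.2e-07), with Otx2 (-5.09 ± 0.30), Fezf1 (-5.08 ± 0.17), Wnt8b (-5.07 ± 0.17) and Six3 (-4.54 ± 0.13) after it. Of 24 forebrain and midbrain genes 23 were lower in the posterior pieces (24 adjusted over the list alone; camera adjusted p = 5.5e-30, and adjusted p = 0.023 with an estimated correlation). All 10 genes of Hox groups 10 to 13 were higher, also adjusted over the list alone (camera adjusted p = 5.1e-21, and adjusted p = 0.019 with an estimated correlation), as were 12 of 14 limb and lateral plate genes, also adjusted over the list alone (camera adjusted p = 5.5e-18, and adjusted p = 0.019 with an estimated correlation). Of 20 genes of ganglia and early neurons, 14 were lower and 2 higher (15 and 4 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.34 with an estimated correlation). The count of calls was 1732 without mutant anterior library 159, 1740 without mutant anterior library 163 and 1593 with only the mutant libraries in the fit.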

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

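Of the tests that weigh explanations here, only the comparison of hypoxia genes between mutant libraries 159 and 163 was written down before its result was seen, and the others were chosen afterwards.

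The genotype effect differed between the regions by limma's test of the difference for 169 genes, which is what drew attention to the genes and lists named here. Differences are the anterior minus the posterior effect in log2(TPM + 1). Hoxb13 (-5.05), En2 (-4.75), Hoxd12 (-3.24), Gfra3 (-3.19) and Uap1l1 (2.66) passed without any 1 library. Aass (2.80) did not pass without wild-type posterior library 153 or 156 (adjusted p = 0.11 and 0.084), nor did Serpinb1a (2.64; 0.10 and 0.080). Hoxd12 was listed at 0 in the wild-type posterior libraries, and with 3 reads there its posterior rise was at least 5.74 on a plain log2 scale. Its anterior means, 0.0663 TPM in the mutant and 0.0627 in the wild type, lay below the 0.159 TPM of 3 reads in the wild-type posterior libraries. The difference of its effects therefore has no such bound. Mir1898 (3.18), a small RNA gene listed at 0 in the wild-type anterior and mutant posterior libraries, had means of 1.28 and 3.29 TPM in the other groups, below the 3.85 TPM that 3 reads would give, so its difference is not resolved from counting error. It did not pass without mutant anterior library 159 (adjusted p = 0.061) or 163 (0.062), wild-type anterior library 153 (0.051) or wild-type posterior library 153 (0.052). Kazald1 (2.65) passed without mutant anterior library 159 and failed without each of the other 7 libraries, with adjusted p between 0.051 and 0.19.

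Gene lists whose effect differed between regions by camera were Hox groups 10 to 13 (adjusted p = 3.4e-16), histones (1.9e-12), ganglia and early neurons (5.3e-08), Hox groups 6 to 9 (4e-07), arch mesenchyme (0.00099), the Fgf pathway (0.0017), the hedgehog pathway (0.0063), yolk sac visceral endoderm (0.0064), hindbrain (0.0064), forebrain and midbrain (0.029), and limb and lateral plate (0.029). With an estimated correlation none of the 11 passed, the smallest being adjusted p = 0.059 for Hox groups 10 to 13. Both Hox lists had a median anterior effect of 0.04 and 0 anterior calls, so their differences mainly restate the posterior effects. The effect was higher in the anterior pieces for histones (2 of 17 genes called, 12 adjusted over the list alone), ganglia and early neurons (3 of 20, and 13 with 3 the other way), Hox groups 6 to 9, yolk sac (0 of 15) and hindbrain (0 of 14). It was higher in the posterior pieces for the other lists, with 3 of 22 arch mesenchyme, 4 of 17 Fgf, 2 of 15 hedgehog and 2 of 14 limb genes called. Forebrain and midbrain genes had 5 calls that way and 1 the other.

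Lists that did not pass without 1 library were forebrain and midbrain (adjusted p = 0.071 without mutant posterior library 159, 0.11 without wild-type anterior library 156, 0.24 without wild-type posterior library 153), hedgehog (0.071 without mutant posterior library 159, 0.058 without wild-type posterior library 153), and limb (0.095 and 0.13 without the same libraries). With voom, forebrain and midbrain (0.59), limb (0.31) and yolk sac (0.31) did not pass. Without both libraries numbered 159, arch mesenchyme (0.074), hedgehog (0.12), yolk sac (0.71) and limb (0.054) did not pass, nor did limb without both numbered 153 (0.11) or with a filter at 5 TPM (0.050). Hindbrain did not pass without mutant posterior library 163 (0.11), wild-type anterior library 156 (0.087) or wild-type posterior library 156 (0.15), nor did yolk sac without mutant posterior library 159 (0.76), wild-type anterior library 156 (0.36) or wild-type posterior library 156 (0.050).

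Of 10 genes of Hox groups 10 to 13, 9 rose in the mutant posterior pieces, with a list median of 2.37, and the set did not pass with an estimated correlation (camera adjusted p = 0.12). A larger share of tail bud and presomitic tissue, with its genes otherwise unchanged, would raise those genes about as much, and as a set they did not rise. The 16 such genes at least 4-fold posterior in the wild type had a median of -0.23 (quartiles -0.56 and 0.50). The wild-type posterior libraries helped to choose these genes and also entered this difference, which can lower it. Wnt8a (2.87), Mixl1 (1.32) and T (0.45) among them passed upwards, and Cer1 (-2.55), Cdx4 (-1.34) and Evx1os (-0.66) downwards. An effect of the genotype on these genes could therefore hide a change of share, so a larger share stays open. Other posterior tissue, such as hindlimb or allantois, was not tested. Scaling is argued against, since the Hox median was 2.31 under median-of-ratios scaling and 2.26 under quantile normalization. A later stage of the mutant embryos stays open: Lin28a, which declines as embryos age, was lower in the mutant posterior pieces by -0.76 (SE 0.12) and Lin28b by -0.53 (SE 0.14; its call was lost without any of 5 of the 8 libraries, with values from -0.69 to -0.38), as either a later stage or an effect of the genotype on these genes could give. The labels give both genotypes the same stage, E9.25 with 9 to 11 somites, and a difference within that range was not tested. An effect of the genotype on posterior Hox genes remains among the open explanations and was not tested.

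Of 30 hypoxia and glycolysis genes, 23 rose in the mutant anterior and 21 in the posterior pieces, with list medians of 0.95 and 0.95, and neither set passed with an estimated correlation (camera adjusted p = 0.75 and 0.61). Displacement by globin and mitochondrial RNA is argued against: the log2 share of TPM left to other genes differed by -0.021 and -0.029 (mutant minus wild type), and by at most 0.005 upwards between any mutant and wild-type library of a region. More blood cells stay open: mutant library 159 minus library 163 gave -0.28 in the anterior and 0.21 in the posterior pieces for hypoxia genes, against 0.69 and 0.80 for globin genes, with 1 library a side. Handling before preservation also stays open, since 8 immediate-early genes had medians of 0.69 and 0.59 and 7 chaperone genes -0.17 and -0.16. An effect of the genotype on oxygen supply may also be involved and was not tested.

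Of 15 visceral endoderm genes, 3 fell in the mutant posterior pieces, with a list median of -1.92, and the set did not pass with an estimated correlation (camera adjusted p = 0.61). Unequal carry-over of yolk sac stays open: the largest difference within a group had a size of 2 (mutant posterior library 159 minus 163, -2), but that spread was seen before the test was chosen and gives no support. In the other groups the differences were 1.54 between wild-type anterior libraries 153 and 156, 0.22 in the wild-type posterior and -0.15 in the mutant anterior pieces. An effect of the genotype on the endoderm stays open, because its test could not tell: 15 pharyngeal and gut endoderm genes had a median of -0.14 with an interquartile range of 0.67, a smaller fall than that of the visceral endoderm list, and an effect on visceral endoderm alone was not tested.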

How the results depend on the processing

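Tests with voom, and without both libraries numbered 159 or both numbered 153, were chosen after the data were seen. Of 13682 values of 562 named-gene results under alternatives, 12257 kept direction and side of the threshold, 1425 passed no longer and 0 reversed. Many alternatives hardly touch a given result. Only 297 of the 562 named-gene results, and 6 of 87 list results, kept both in every alternative. Of 1277 values of 87 list results, 1107 kept both, 167 passed no longer and 3 reversed: the heart list in the posterior pieces, without mutant posterior library 159 (adjusted p = 0.92), wild-type posterior library 153 (0.93) or both libraries numbered 159 (0.89), where the cause was not tested. Its adjusted p ranged from 4.3e-06 (without mutant posterior library 163) to 0.93 over the libraries left out.

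Requiring a 2-fold change left 926 anterior, 625 posterior, 1109 wild-type region and 1171 mutant region calls, by construction. Without a filter on low values, with more genes tested, 954 posterior and 55 interaction genes passed. With only the groups compared, and so fewer libraries, 934 posterior and 1593 mutant region genes passed, but 3897 anterior and 2722 wild-type region genes. Library weights gave 1102 posterior and 2099 mutant region calls, but 5188 anterior and 3242 wild-type region calls (the cause was not tested). Without both libraries numbered 153, calls were 652 anterior, 180 posterior, 0 interaction (limma; 1031 at an unadjusted p under 0.05, no other tool run on that subset), 573 wild-type region and 1708 mutant region, and 111 genes were shared between regions. With a threshold of 0.1, 1972 were shared. With an estimated correlation, 0 anterior, 0 posterior, 0 interaction, 3 wild-type region and 3 mutant region lists passed.

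Leaving out 1 library at a time gave 1545 to 4563 anterior, 383 to 1832 posterior, 20 to 209 interaction, 1182 to 2880 wild-type region and 1732 to 2770 mutant region calls, and 298 to 1104 shared genes. Lists past the threshold numbered 10 to 14 anterior, 13 to 20 posterior, 8 to 15 interaction, 20 to 26 wild-type region and 23 to 27 mutant region. Nr6a1 ranged from 0.02 to 0.27 in the anterior and from -0.47 to -0.03 in the posterior pieces. With voom, 4608 anterior, 2849 posterior and 181 interaction genes passed.

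The labels do not say what equal replicate numbers share, and both libraries numbered 159 had Xist (25.3 and 30.9 TPM, and at most 0.0749 in the other 6). As a check of pairing, deviations of same-numbered libraries from their group means correlated at 0.136 in the mutant and 0.022 in the wild type. With the number as a random block, 290 interaction genes passed (134 with the higher effect in the anterior, 156 in the posterior pieces), 3928 anterior and 1910 posterior. With it as a fixed block, 115 interaction, 2404 wild-type region and 2617 mutant region genes passed, the limb list of the interaction no longer passed (adjusted p = 0.053), the only list call the block ended, and the genotype effects had no value, nor had the interaction with only the groups compared. Depth limits genes near 3 reads, a TPM of 0.2 to 0.403 for a gene of 1 kb.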

Other observations

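The tests of single genes and lists here were fixed before the data were examined, and the tests without both libraries numbered 159 were chosen only after the result was seen.

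Zic5, a zinc finger gene of the neural plate border, rose in the mutant by 1.49 ± 0.11 in the anterior and 1.23 ± 0.11 in the posterior pieces. The list of 14 border genes had 5 rises and 2 falls in the anterior (6 and 2 adjusted over the list alone) and 4 and 1 in the posterior pieces (7 and 2), and did not pass as a set (camera adjusted p = 0.065 in each). Wnt8a, an early posterior Wnt ligand, rose in both regions (2.53 ± 0.24 and 2.87 ± 0.24), from 4.61 ± 1.1 to 39.6 ± 3.1 TPM in the posterior pieces. Aldh1a3, which makes retinoic acid, rose in the anterior pieces (1.59 ± 0.15) with Cyp26a1 (1.76 ± 0.15), which degrades it, while Aldh1a2 fell (-1.45 ± 0.24). The retinoic acid list did not pass as a set (camera adjusted p = 0.35 anterior, 0.82 posterior).

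Imprinted genes went both ways, with 4 rises and 5 falls of 21 in the anterior and 4 and 1 in the posterior pieces, the same counts adjusted over the list alone (camera adjusted p = 0.76 and 0.19). Plagl1 rose in both regions (1.65 ± 0.12 and 1.60 ± 0.12), from 63.2 ± 3.1 to 194 ± 0.52 TPM in the posterior pieces, and Phlda2 fell there (-1.65 ± 0.20). Of 20 endothelial genes, 4 rose and 1 fell in the anterior and 2 rose and 1 fell in the posterior pieces (5 and 2, and 5 and 1, adjusted over the list alone; camera adjusted p = 0.67 and 0.11). Cldn5 rose by 1.25 ± 0.15 and Pecam1 by 1.11 ± 0.14 in the posterior pieces, where Etv2, an early regulator of the endothelial lineage, fell (-1.39 ± 0.16). Of 20 p53 target genes, 7 rose and 2 fell in the anterior and 4 and 1 in the posterior pieces (7 and 3, and 5 and 1, adjusted over the list alone; camera adjusted p = 0.28 and 0.093), and Cdkn1a rose from 18.6 ± 0.61 to 34.3 ± 2.7 TPM in the posterior pieces. Germ line genes had 3 rises of 9 in the anterior and 2 in the posterior pieces and no falls (5 and 2 adjusted over the list alone; camera adjusted p = 0.071 and 0.55), with Nanos3 rising in the posterior pieces (1.79 ± 0.26).

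Xist was at 25.3 TPM in mutant anterior library 159 and 30.9 in mutant posterior library 159, and at most 0.0749 in the other 6 libraries. Ddx3y, on the Y chromosome, was at 0.155 and 0.0768 TPM in those libraries and between 26.2 and 39.4 in the other 6. Leaving out both libraries numbered 159 left a lone mutant library in each region, with the spread taken from the wild type alone. The number of calls without them therefore does not measure the effect of sex.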
